A study of Mus musculus with 4 samples.

How the data were processed

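Per the labels' protocols, back skin of newborn mice was digested with collagenase and trypsin, stained and sorted, and total RNA was isolated from the sorted cells. 10 ng of total RNA was reverse transcribed and amplified with the Ovation RNA-seq System V2, libraries were made from 100 ng of sonicated cDNA, and single reads of 100 nucleotides were taken on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name TopHat2 2.0.13, Cufflinks 2.2.1, HTSeq 0.6.1 and DESeq2 1.6.3 with the genome build mm10, without giving their role or order. The annotation, the strand setting and the tool that made the counts are not given in the sources used here. The authors deposited raw read counts per gene symbol, not normalized, as whole numbers for the same symbols in each of the 4 libraries. Of these symbols 4758 had 0 counts in every library.

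The groups were taken from the sample labels, with 2 control libraries and 2 libraries of the mutant genotype, and replicate numbers from the same labels. At least 99.89% of each library's counts fell in tested genes. The ribosomal gene Rn45s was the most abundant gene in each library, with 3.27% to 5.48% of the counts. Log2 CPM correlated at 0.974 between the control libraries and 0.969 between the mutant libraries, and at 0.936 to 0.944 between control and mutant libraries, across genes, which are not independent replicates. The counts of replicates differed by more than sampling noise, so each library counted as 1 sample. The chi-square per degree of freedom was 13.1 between controls and 41.8 between mutants. By their reads the mutant pair was 1 male and 1 female library, and sex-linked genes were kept in this chi-square.

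Genes were filtered with filterByExpr at its defaults (a minimum count of 10 and a minimum total of 15), which left 14550 genes. Libraries were scaled with TMM (factors 0.988, 0.974, 0.985 and 1.05). The groups were compared with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test (glmQLFit and glmQLFTest, without a block), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are mutant over control, and their SE comes from the fitted coefficient and its F statistic. CPM values are counts over the TMM-scaled library size, given as mean ± SD over n = 2 libraries. Where a group had no reads, the fold is a lower bound against a floor of 3 counts over the group, and where it had 1 to 3 reads the ratio of pooled counts has an exact binomial interval at 95%. Reads carry no molecular identifiers, so intervals and floors cover counting error only. On simulated counts for the same comparison, with 50 of 14550 genes changed at each size, the test recovered 4%, 46%, 78% and 84% of changes of 1.5-, 2-, 4- and 8-fold, with 8 false calls. Small changes were therefore mostly missed in the simulation. It changed fewer genes than the 977 called in the data. The Benjamini-Hochberg cutoff eases as more genes are called, so recovery in the data may be higher than in the simulation.

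Before the data were examined, 26 gene lists, the tests, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested genes, 24 of them, were tested with camera at a preset correlation of 0.01, adjusted over these lists, and beside it with an estimated correlation and with fry. The text names Ring1 and Rnf2, and the 8 largest increases and 8 largest decreases among called genes with a mean of at least 1 CPM and groups that do not overlap, leaving out predicted genes, clone names and small RNAs. It also names up to 2 higher and 2 lower members of smallest p of each called list, and up to 1 of each of every other list. Merkel, Hox, inhibitor and basal lists without a called member would have been shown by their 2 members of highest mean CPM, which no list needed. Any other gene named was chosen after its values were seen. Sprr1b, Krt17, Cdkn1a, Cdh3, Thy1, Perp and Foxd3 are each in 2 lists. Members of close families (Krt6, Stfa, Sprr, Lce) may share reads, and the globin genes Hba-a1 and Hbb-bs had 0 counts in every library. Gene coordinates, GC content and transcript length came from GENCODE M21 on GRCm38, matched by symbol for 97.2% of the symbols and 97.8% of the tested genes.

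The alternatives were DESeq2 1.42.0, limma-voom (limma 3.58.1), RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 2 libraries, the earlier and the robust quasi-likelihood fit, and glmTreat at a fold change of 1.5. Each library was also left out in turn, where the arm with 1 library is assumed to vary like the other. Offsets from a loess fit (span 0.5) of each library on GC content and length were used alone and together with the replicate number as a block. Calls near the targeted genes were compared by Fisher's exact test within 10 Mb, with the targeted genes left out.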

Results

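RNA was sequenced from epidermal cells of newborn mice at postnatal day 0. Back skin was digested, and cells of the epidermis between the hair follicles were sorted as positive for EpCAM and Sca1 and high for α6-integrin, a gate that enriches for epidermal progenitors. The study set mutant against control epidermis to learn what the catalytic activity of PRC1, the Polycomb complex that ubiquitinates histone H2A, does in skin. Mutant mice lacked Ring1 (the protein Ring1a) and carried a null allele of Rnf2 (the protein Ring1b) over the I53A allele, whose product is catalytically inactive. The comparison does not separate the inactive allele from the absence of Ring1 or from the null Rnf2 allele. There were 2 control and 2 mutant libraries. The total counts were 17010432 and 15505018 in control replicates 1 and 2, and 15966412 and 21543385 in mutant replicates 1 and 2. Of the genes counted, 14550 passed the low-count filter and were tested.

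Ring1 transcripts fell to 9.63% of the control level in the mutant epidermis, while Rnf2 did not pass the test in either direction. Of 34 tested developmental regulators of other lineages 14 rose, among them Six2, Sim2, Lmx1a, Vax1 and Tbx3, while Sox21 fell and 19 did not pass the test. The set passed with a preset correlation but not with an estimated one (camera adjusted p = 5.26e-12 and 0.328). The estimate, -0.027, lay below the preset 0.01. Genes of the contractile cytoskeleton (Myh10, Tpm1), connexins (Gjb2, Gjb6), the hair follicle regulator Lhx2, the stress keratin Krt6a and the cell cycle inhibitor Cdkn1c also rose. The hair protein gene Tchh and the protease inhibitor gene Serpinb7 fell. Proliferation genes held no member that passed the test in either direction.

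Ring1 lies on chromosome 17 from 34020792 to 34024680 on the minus strand of GRCm38, the assembly also called mm10. Its levels were 24.2 and 33.3 CPM (counts scaled to library size) in control replicates 1 and 2, from 406 and 502 counts, and 2.54 and 2.91 CPM in mutant replicates 1 and 2, from 40 and 66 counts. The mean was 28.7 ± 6.43 CPM (SD, n = 2) in controls and 2.73 ± 0.257 CPM (SD, n = 2) in mutants, a log2 fold change of -3.38 ± 0.31 (SE, adjusted p = 0.000172, edgeR quasi-likelihood test). Rnf2 lies on chromosome 1 from 151458004 to 151500955 on the minus strand. Its levels were 58.5 and 45.8 CPM in control replicates 1 and 2 and 58.9 and 59.1 CPM in mutant replicates 1 and 2, a log2 fold change of 0.18 ± 0.17 (SE, adjusted p = 0.681). The mean did not fall (52.2 CPM in controls and 59.0 CPM in mutants), although a null allele without a transcript would lower it, and transcription from each allele was not tested. A count per gene does not read the substituted base of the I53A allele, so the Rnf2 level does not check the genotype. Among the 25 tested components of PRC1, Ring1 fell and Bcor, a subunit of a variant PRC1, rose from 120.0 to 179 CPM (log2 fold change 0.58 ± 0.14, adjusted p = 0.0327). Of the 12 tested PRC2 components, Jarid2 rose (log2 fold change 0.52 ± 0.13, adjusted p = 0.0468). Neither list moved as a set (camera adjusted p = 0.687 and 0.695), and adjusted over the list alone 1 PRC1 component was higher and 1 lower, and 2 PRC2 components were higher. The calls of Bcor and Jarid2 did not hold without control replicate 1 (adjusted p = 0.314 and 0.399), without control replicate 2 (0.315 and 0.351) or with offsets for GC content and transcript length (0.343 and 0.387), and Jarid2 also missed the threshold with limma-voom (adjusted p = 0.0505).

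**Figure D1:**
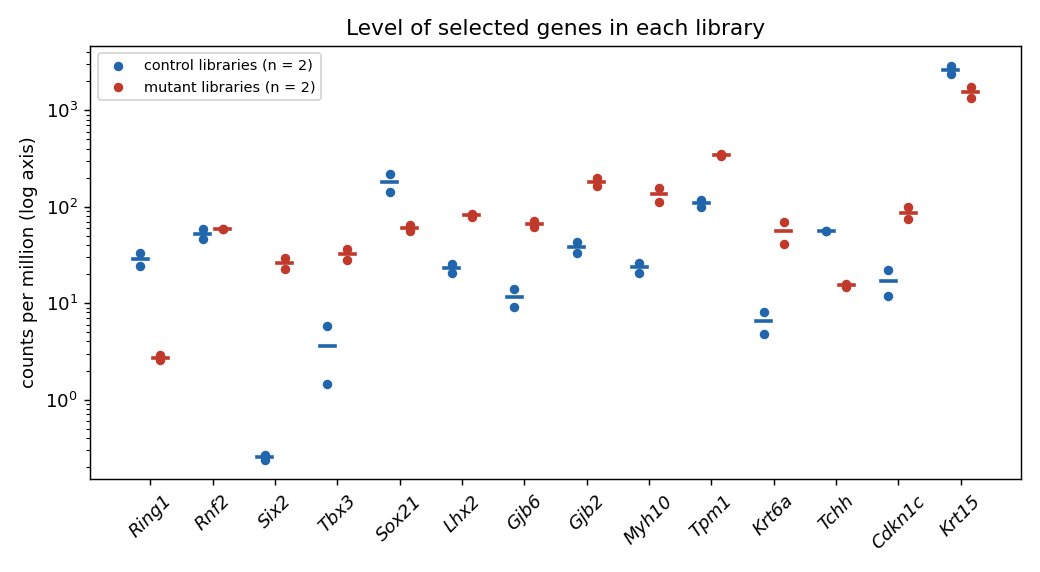
CPM (log axis) of 14 genes in each library, with control libraries in blue, mutant libraries in red and a bar at the mean of each group (n = 2). Ring1 is at 2.54 and 2.91 CPM in the mutant libraries against 24.2 and 33.3 CPM in the controls, and Rnf2 is between 45.8 and 59.1 CPM in all libraries.

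In all, 977 of 14550 tested genes differed between mutant and control epidermis (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 826 were higher and 151 were lower in the mutant, so that 84.5% of the calls were increases. The changes were of at least 2-fold for 689 of the genes that rose and for 81 of those that fell. The control mean was under 1 CPM for 137 of the genes that rose (16.6%). All 977 genes had groups that did not overlap, as had 47.9% of all tested genes, against 33.3% that chance gives for 2 against 2 libraries. Offsets for GC content and transcript length gave 730 higher and 701 lower genes, and moved the median log2 fold change of all genes by -0.13. Without control replicate 1 the test called 297 genes and without control replicate 2 it called 326, against 1489 without mutant replicate 1 and 1520 without mutant replicate 2.

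**Figure D2:**
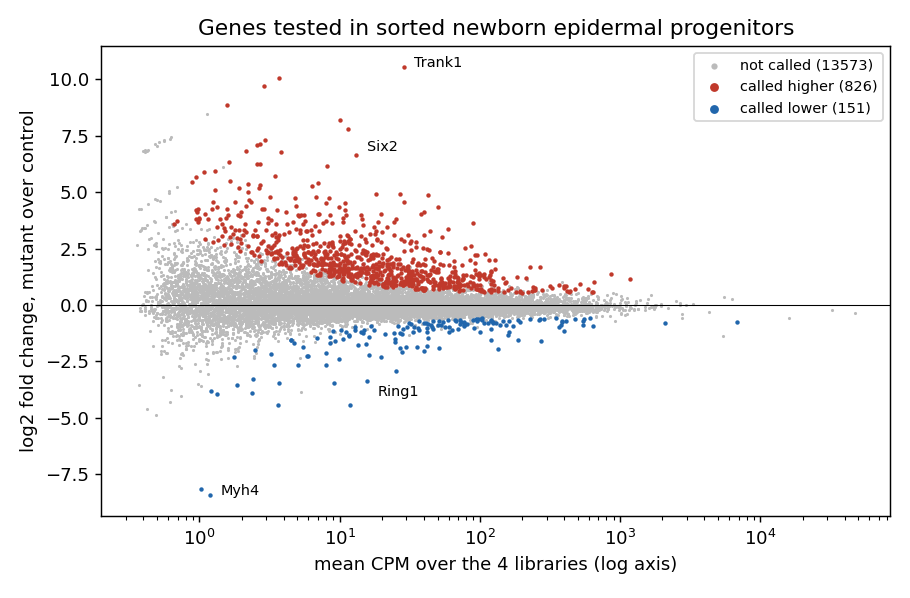
Log2 fold change of mutant over control for the 14550 tested genes against their mean level in CPM (log axis), with 826 genes called higher in red, 151 called lower in blue and the rest in grey. Most calls lie above 0, and genes with no reads in a group, such as Myh4, are drawn at the fitted value, which depends on the prior count.

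The largest increases were of genes that were almost silent in control epidermis. Trank1 had 0 and 1 counts in control replicates 1 and 2 and 57.2 ± 6.16 CPM (SD, n = 2) in mutants, a ratio of 1848 with a 95% counting interval from 331 to 73035. Kcnip1, which encodes a protein that binds potassium channels, had no reads in the controls and was at least 84.7-fold higher in the mutants, against a floor of 3 counts over the group. Vax1, a homeobox gene of the ventral forebrain and eye, was likewise at least 63.9-fold higher. Adgrb1, an adhesion receptor known from the brain, rose to 20.1 ± 6.26 CPM (ratio 333, interval 91.9 to 2754), and Rbm46, an RNA-binding protein of germ cells, to 22.9 ± 1.34 CPM (ratio 245, interval 83.6 to 1191). The amino acid transporter gene Slc7a10, the LIM homeobox gene Lmx1a and the transcription factor gene Sim2 reached 5.87, 5.42 and 5.16 CPM in the mutants from 1 read each in the controls. Their ratios were 198 (interval 35.3 to 7871), 169 (29.9 to 6690) and 168 (29.8 to 6657). These 8 genes had adjusted p from 1.07e-05 to 0.00431 and held past the threshold without each library in turn.

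Among the largest decreases, Serpinb7, a serine protease inhibitor of the epidermis, fell from 16.8 ± 2.03 to 1.44 ± 0.773 CPM (SD, n = 2 each; log2 fold change -3.46 ± 0.39, adjusted p = 0.000653). The transglutaminase gene Tgm7 fell from 4.41 to 0.311 CPM (log2 fold change -3.90 ± 0.66), the epithelial chemokine gene Ccl28 from 3.42 to 0.311 CPM (-3.55 ± 0.71), and Abhd12b from 6.77 to 0.585 CPM (-3.48 ± 0.54). Hephl1, a relative of the ferroxidase hephaestin, fell from 2.51 to 0.171 CPM (-3.93 ± 0.85), and the cytochrome P450 gene Cyp2g1 from 7.06 to 0.284 CPM (-4.44 ± 0.99). Myh4, the myosin of fast skeletal muscle, had 57 and 21 counts in control replicates 1 and 2 and none in the mutants, so that it was at least 31.3-fold lower against the floor of 3 counts over the group. Ring1 completed this group of 8. Several of these calls depended on a library: without control replicate 1 those of Myh4, Hephl1 and Ccl28 were lost (adjusted p = 0.183, 0.0677 and 0.150), without control replicate 2 those of Cyp2g1, Hephl1, Tgm7, Ccl28 and Abhd12b (0.228, 0.213, 0.0612, 0.0635 and 0.0607), and without mutant replicate 2 that of Hephl1 (0.0702). With limma-voom, Cyp2g1 and Hephl1 missed the threshold (adjusted p = 0.155 and 0.0642).

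Developmental regulators of other lineages, a list fixed before the data were examined, passed as a set with a preset correlation (camera adjusted p = 5.26e-12) but not with an estimated one (adjusted p = 0.328). Of 117 members 83 were not tested, and of 34 tested members 14 rose, 1 fell and 19 did not pass the test. Adjusted over the list alone, 18 rose and 2 fell. Six2, a regulator of kidney and craniofacial progenitors, rose from 0.252 ± 0.0191 to 26.1 ± 5.18 CPM (SD, n = 2 each; log2 fold change 6.65 ± 0.47, adjusted p = 3.36e-05). Tbx3, a T-box factor of limb and mammary gland, rose from 3.62 ± 3.05 to 32.2 ± 5.69 CPM (log2 fold change 3.13 ± 0.41, adjusted p = 0.00136). Sox21, a factor also needed in hair, fell from 179 ± 52.3 to 60.2 ± 5.50 CPM (log2 fold change -1.57 ± 0.20, adjusted p = 0.00124). The median log2 fold change over the list was 1.14, also with Vax1 at its bound. Members nearly silent in controls pass the low-count filter only through the mutant libraries, so silent members that did not rise are left out. Of the 18 members that the control libraries alone would keep, 8 rose and 1 fell, and 5.12% of other such genes rose. Without control replicate 1 or 2, 8 and 7 members were called higher, and the camera adjusted p was at most 1.87e-09 without each library in turn.

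Hox genes moved in both directions. Of 39 members 13 were not tested, and of 26 tested members 6 rose and 2 fell, or 2 and 2 of the 22 that the control libraries alone would keep, and adjusted over the list alone 7 rose and 5 fell. Hoxd9 rose from 0.126 ± 0.00953 to 4.30 ± 0.147 CPM (SD, n = 2 each; log2 fold change 5.03 ± 0.74, adjusted p = 0.00139). Hoxc4 fell from 65.5 ± 4.21 to 35.6 ± 0.121 CPM (log2 fold change -0.88 ± 0.16, adjusted p = 0.00884). As a set the list was not called (camera adjusted p = 0.815), with a median log2 fold change of -0.08 and a mean of 0.59. Without control replicate 1 or 2 the calls of Hoxd9 (adjusted p = 0.0620 and 0.0522) and Hoxc4 (0.0991 and 0.161) were lost, and 1 Hox gene was called in each case.

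**Figure D3:**
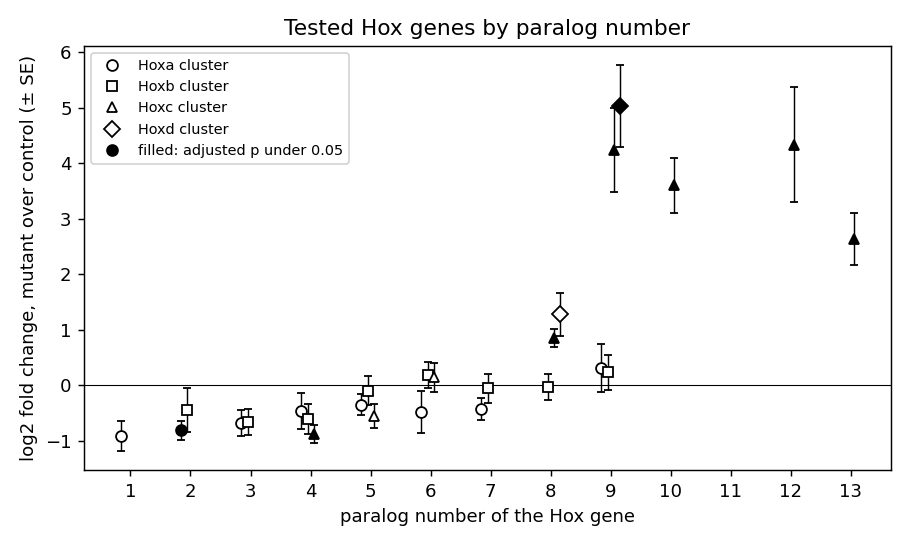
Log2 fold change (mutant over control, ± SE) of the 26 tested Hox genes against paralog number, with a marker shape for each cluster and filled markers for genes past the threshold. Hoxd9 and 5 genes of the Hoxc cluster lie above 0 among the filled markers, and Hoxa2 and Hoxc4 below 0.

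**Figure D4:**
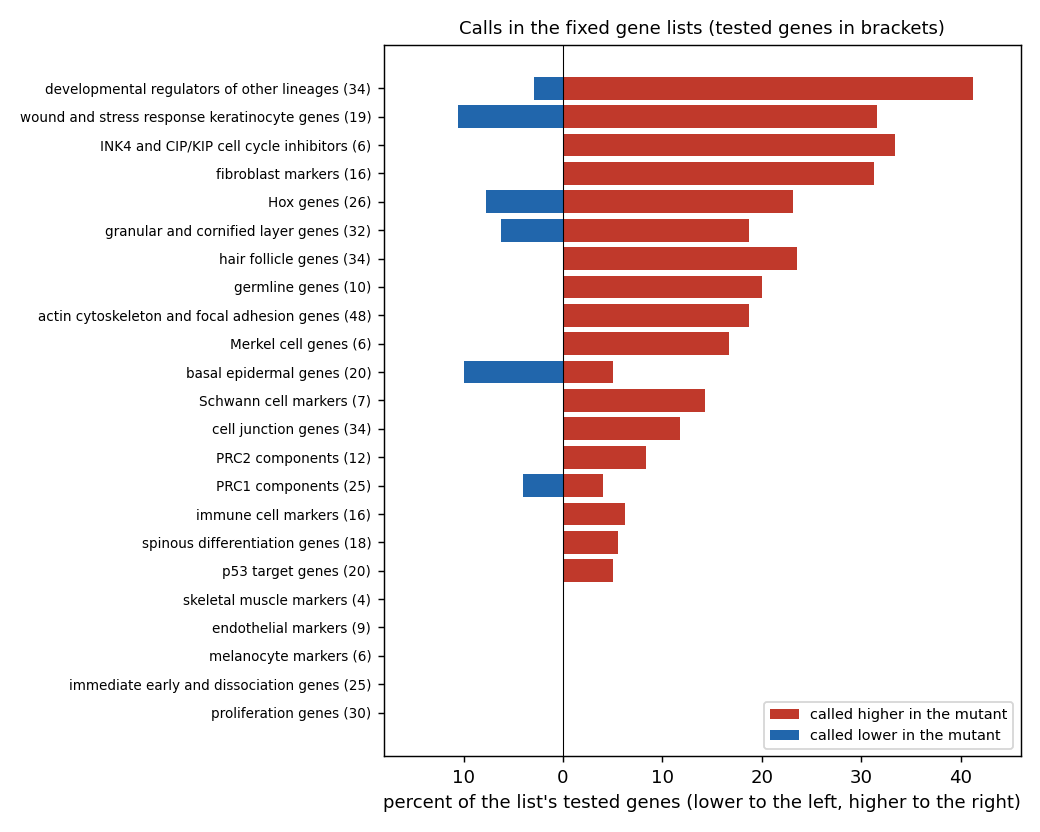
Percent of the tested genes of fixed lists that were called higher (red, to the right) or lower (blue, to the left) in the mutant, for lists with at least 3 tested genes, whose number is in brackets. Developmental regulators of other lineages stand highest, with 14 of 34 genes called higher.

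Hair follicle genes included 8 members that rose among 34 tested, with none lower, and 14 higher and 1 lower adjusted over the list alone. Gjb6, a connexin, rose from 11.6 ± 3.42 to 66.4 ± 6.51 CPM (SD, n = 2 each; log2 fold change 2.51 ± 0.23, adjusted p = 0.000172). Lhx2, a LIM homeobox regulator of hair follicle stem cells, rose from 23.0 ± 3.65 to 81.8 ± 4.57 CPM (log2 fold change 1.83 ± 0.18, adjusted p = 0.000299). Actin cytoskeleton and focal adhesion genes included 9 that rose among 48 tested, with none lower, and the same numbers adjusted over the list alone. Myh10, a nonmuscle myosin heavy chain, rose from 23.5 ± 4.04 to 134 ± 31.8 CPM (log2 fold change 2.52 ± 0.21, adjusted p = 0.00012), and Tpm1, a tropomyosin, from 108 ± 13.9 to 345 ± 11.6 CPM (log2 fold change 1.67 ± 0.15, adjusted p = 0.000166). The camera adjusted p was 0.00163 for the hair follicle list (adjusted p = 0.727 with an estimated correlation) and 0.00402 for the actin list (adjusted p = 0.657 with an estimated correlation). Fibroblasts express many actin cytoskeleton genes too, and 5 of 16 fibroblast markers rose in the same libraries. Both set calls were lost without control replicate 1 (adjusted p = 0.0715 for each) and with the GC content and length offsets (0.0653 and 0.0618). Without control replicate 1 or 2, 3 hair follicle genes and 3 or 4 actin genes were called higher. With the offsets 5 hair follicle genes were higher and 3 lower, and 6 actin genes were higher and 0 lower.

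Wound and stress response genes of keratinocytes included 6 that rose and 2 that fell among 19 tested, and 8 and 3 adjusted over the list alone. Without control replicate 1 the counts were 1 higher and 2 lower, and without control replicate 2 they were 3 and 0. Krt6a, a keratin induced in wounds, rose from 6.49 ± 2.35 to 55.3 ± 20.1 CPM (SD, n = 2 each; log2 fold change 3.11 ± 0.32, adjusted p = 0.000411). Stfa3, a stefin, fell from 412 ± 119 to 134 ± 54.3 CPM (log2 fold change -1.61 ± 0.27, adjusted p = 0.00521, and 0.0836 without control replicate 2). Krt6a has the near-identical copy Krt6b, and Stfa3 has close paralogs, so reads between these copies are uncertain. The set was not called (camera adjusted p = 0.0517). It passed in 7 of 13 other settings, among them without control replicate 2, without mutant replicate 1 and with the offsets (0.00518).

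Granular and cornified layer genes rose in 6 and fell in 2 of 32 tested members, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.526). The counts were 1 higher and 2 lower without control replicate 1, 2 and 1 without control replicate 2, and 6 and 4 with the offsets. Scel, the cornified envelope protein sciellin, rose from 53.1 ± 16.0 to 125 ± 20.1 CPM (SD, n = 2 each; log2 fold change 1.23 ± 0.21, adjusted p = 0.00639, and 0.103 without control replicate 2). Tchh, trichohyalin of the inner root sheath, fell from 56.0 ± 0.192 to 15.4 ± 0.776 CPM (log2 fold change -1.87 ± 0.18, adjusted p = 0.000278). Of 18 tested spinous genes, Grhl3, a transcription factor of barrier formation, rose (log2 fold change 0.83 ± 0.20, adjusted p = 0.0333), and 3 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.794). The balance of spinous calls turned with the library left out, with more higher without mutant replicate 1 and more lower without mutant replicate 2. Of 20 tested basal genes 1 rose and 2 fell, or 1 and 3 adjusted over the list alone (camera adjusted p = 0.566). Igfbp3, which binds insulin-like growth factors, rose from 50.4 ± 10.4 to 123 ± 3.37 CPM (log2 fold change 1.29 ± 0.17, adjusted p = 0.00153). Krt15, a keratin of basal cells, fell from 2645 ± 372 to 1536 ± 282 CPM (log2 fold change -0.78 ± 0.18, adjusted p = 0.0254). The basal list passed as a set, lower, only with the GC content and length offsets (0.027), where 1 basal gene was higher and 6 lower, and 2 spinous genes were higher and 3 lower. The call of Grhl3 was lost without control replicate 1 or 2 (adjusted p = 0.0920 and 0.380), as were those of Krt15 (0.389 and 0.134), and Igfbp3 missed the threshold without control replicate 1 (0.0524).

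Cell junction genes rose in 4 of 34 tested members and fell in none, also adjusted over the list alone. With the offsets 3 were higher and 4 lower, and without control replicate 1 or 2, 2 and 1 were higher. Gjb2, a connexin of the same chromosomal region as Gjb6, rose from 38.2 ± 6.66 to 181 ± 26.6 CPM (SD, n = 2 each; log2 fold change 2.25 ± 0.18, adjusted p = 8.88e-05). The set was not called (camera adjusted p = 0.129), although it passed without mutant replicate 1 (0.0358). Of 10 tested germline genes 2 rose, or 3 adjusted over the list alone, among them Tdrd1, a tudor protein of the piRNA pathway, from 35.8 ± 14.2 to 82.0 ± 9.30 CPM (log2 fold change 1.20 ± 0.24, adjusted p = 0.0144, and 0.162 without control replicate 1). The germline set was not called (camera adjusted p = 0.0517). It passed in 8 of 13 other settings, among them without control replicate 2, without mutant replicate 1 and with the offsets (0.0145). Only 10 of 29 germline genes were tested. Members nearly silent in controls pass the low-count filter only through the mutant libraries, so silent members that did not rise are left out.

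Of the INK4 and CIP/KIP cell cycle inhibitors, 2 of 6 tested rose, and 2 were higher and 1 lower adjusted over the list alone (camera adjusted p = 0.566). Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, rose from 17.0 ± 7.13 to 86.3 ± 17.0 CPM (SD, n = 2 each; log2 fold change 2.33 ± 0.27, adjusted p = 0.000697). Cdkn2b was the other inhibitor that rose (adjusted p = 0.037, edgeR quasi-likelihood test). Its log2 fold change was 2.80 with the GC content and length offsets, and it missed the threshold with limma-voom (adjusted p = 0.0934). Cdkn2a, a known Polycomb target, had 0 counts in every library. Its floor of 3 counts per library was 0.132 to 0.199 CPM. The p53 target Trp53inp1 rose (log2 fold change 1.08 ± 0.28, adjusted p = 0.0472), and no p53 target passed adjusted over the list alone among 20 tested (camera adjusted p = 0.566). Its call was lost without control replicate 1 (0.129), control replicate 2 (0.402) or mutant replicate 1 (0.0883), and with limma-voom (0.0795). Among 30 tested proliferation genes and 25 tested immediate early and dissociation genes the edgeR test called 0, also adjusted over each list alone (camera adjusted p = 0.566 and 0.672). Without mutant replicate 2 some proliferation genes were called lower and some immediate early genes higher. Without mutant replicate 1 some immediate early genes were called lower instead, so their direction depended on the library left out. The immediate early set passed without control replicate 2. Only 6 of 18 Merkel cell genes were tested, so the list test leaves most of them out. Among 6 tested Merkel cell genes Piezo2, a mechanosensitive channel, rose (log2 fold change 1.44 ± 0.27, adjusted p = 0.00924; 0.0888 and 0.134 without control replicates 1 and 2), with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.566).

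Markers of other skin cell types were read in the same libraries, although the gate was set to enrich for epidermal progenitors. Fibroblast markers rose in 5 of 16 tested members and fell in none, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000111; adjusted p = 0.657 with an estimated correlation). Col5a1, a collagen chain, rose from 90.0 ± 8.99 to 204 ± 0.958 CPM (SD, n = 2 each; log2 fold change 1.18 ± 0.14, adjusted p = 0.000995), and Fbn1, fibrillin, from 67.7 ± 1.61 to 152 ± 16.5 CPM (log2 fold change 1.17 ± 0.15, adjusted p = 0.00124). Fewer fibroblast markers were called without either control library. More were called without mutant replicate 2, where a marker was also called lower. Thy1, which is also in the immune list, rose to 56.7 ± 13.9 CPM (log2 fold change 1.51 ± 0.22, adjusted p = 0.0027, and 0.0732 without control replicate 1). It was the 1 immune marker called of 16 tested, with 2 higher adjusted over the list alone (camera adjusted p = 0.224; 0.0178 without control replicate 2 and 0.00915 without mutant replicate 1). Of 7 tested Schwann cell markers Mbp rose (log2 fold change 1.13 ± 0.24, adjusted p = 0.0169; 0.0603 and 0.238 without control replicates 1 and 2), also adjusted over the list alone (camera adjusted p = 0.659). No member was called among 6 melanocyte, 9 endothelial and 4 skeletal muscle markers (camera adjusted p = 0.695, 0.659 and 0.224). Adjusted over the list alone 1 muscle marker was lower, and the endothelial set passed without control replicate 2 (0.0197). The erythroid and sex-linked lists had 1 tested gene each, Alas2 and Xist, neither of them called (log2 fold change -0.45 ± 0.30 and -1.38 ± 1.41, adjusted p = 0.496 and 0.694).

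Of the 24 lists that could be tested, 4 passed with the preset correlation and none with an estimated correlation. With an estimate, camera also uses the few degrees of freedom that 4 libraries leave, which makes it hard for any list to pass. The estimate was -0.027 for the developmental regulators and 0.00698 for the actin genes, under the preset 0.01. Correlation among members therefore does not account for these losses. For hair follicle genes and fibroblast markers the estimate was 0.078 and 0.0743. With fry's directional test 1 list passed, the developmental regulators (adjusted p = 0.0192). Fry's test for change in either direction passed for 18 lists. The median and the mean or the camera direction differed in sign for the PRC2, Hox, INK4 and CIP/KIP and proliferation lists. The samples' labels do not say whether the libraries came from separate animals. The mutant libraries read as 1 male and 1 female, so they did not come from the same animal, while this stays open for the controls. P-values therefore measure only the spread between these libraries. Antisense and overlapping genes were not separated, because the strand setting of the counting is not given in the sources used here.

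Targeted alleles can carry flanking DNA of another strain, so genes near Ring1 and Rnf2 were compared with the rest. Within 10 Mb of either locus 24 of 405 tested genes were called (5.93%), against 945 of 13826 elsewhere (6.83%). The odds ratio was 0.859 with a 95% interval from 0.54 to 1.31 (Fisher's exact test, two-sided, p = 0.548). The called genes nearest to the loci were H2-K1 beside Ring1 (log2 fold change 1.40 ± 0.19, adjusted p = 0.00163), followed by Psmb8 (1.75 ± 0.44, adjusted p = 0.04), and Fam129a beside Rnf2 (1.11 ± 0.23, adjusted p = 0.0164). These 3 genes were chosen for naming after their values were seen, and an effect of flanking DNA on them was not tested.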

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

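In this part, the tests with thinned libraries, of the fibroblast markers, of the offsets with the centre held, of glmTreat with the offsets and without X and Y genes were chosen after the result was seen.

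Mutant replicate 1 held 5220 reads of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, which the low-count filter removed from the comparison. The other libraries held 3, 4 and 12 such reads (control replicates 1 and 2 and mutant replicate 2). Xist had 173 counts in mutant replicate 1 and at least 121977 in each of the others, so this library read as male and the rest as female. Without this library 96.1% of the called genes stayed past the threshold. That cannot show whether calls rest on it, because the spread then came from the control pair alone, which differed less than the mutant pair did. X-linked genes were called at an odds ratio of 1.09 (95% interval 0.747 to 1.54, Fisher's exact test), so that a small excess of X-linked calls cannot be told apart from none at this number of genes, and without X and Y genes 941 genes were called.

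More genes were called higher (826) than lower (151). After thinning the libraries to the smallest total 84.1% of the calls stayed higher, which argues against depth, while RLE and upper-quartile scaling (at least 84.1%) hardly moved the median of all genes (-0.00182 with RLE) and so leave the choice of scaling open. Offsets for GC content and length brought the share to 51.0%, and together with the replicate number as a block to 46.5% (1041 higher, 1198 lower), but they also moved the median of all genes by -0.13, so this setting alone cannot be told apart from a shift of the centre. With the offsets held at a median of 0 or fitted robustly the share was at least 73.4%, and with glmTreat and the offsets as first fitted it was 80.8%, so neither the trend nor a shift of the centre by this much could account for the whole excess, though part of the small changes may follow them. Loss of PRC1 activity in the mutant was not tested as the source of the excess and stays open. The same holds for the absence of Ring1, for the null Rnf2 allele and for a change that shifts all genes. No scaling here could show such a shift.

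Of 16 tested fibroblast markers 5 were called higher and 11 were not called. The set passed with a preset correlation, but not with an estimated correlation (adjusted p = 0.657) or with fry's directional test (0.155). The median log2 fold change of all tested members was 0.50, with 15 of 16 above 0 and a range from -0.19 (Postn) to 1.51 (Thy1), against 0.25 for 30 melanocyte, endothelial and immune markers (exact Wilcoxon rank-sum test, p = 0.104). Members of a list do not vary independently, and the markers of the other cell types lay above 0 as well. A larger share of fibroblast RNA cannot be told apart from a change within the sorted cells, since both raise these genes in the same 2 mutant libraries.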

How the results depend on the processing

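The alternatives with offsets of median 0, a robust loess, glmTreat with offsets, thinning and without X and Y genes were chosen after seeing the data. Of 977 called genes, at least 83.3% stayed past the threshold in each of the settings that keep all libraries and test against no change, and no shared call turned its direction in any setting. The count stayed within 1.5 times, from 835 with limma-voom to 1431 with the GC content and length offsets, apart from the following. Leaving out 1 library gave 297 to 1520 calls, with 258 to 1131 higher and 34 to 389 lower, the fewest without a control. With 1 control left, the spread comes from the mutant pair alone, and that pair differed more than the controls did. Mutant replicate 1 read as male and mutant replicate 2 as female, while both controls read as female. The part of the difference that comes from sex was not separated. The genes that fell numbered 232 with DESeq2 and 701 with the offsets, and 315 with the offsets held at a median of 0. The cause was not tested beyond the shift of the median given above. Testing against a fold change of 1.5 gave 523 calls (473 higher, 50 lower), and 421 with the offsets (340 higher, 81 lower), fewer by construction.

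The labels do not say that replicate numbers mark a shared litter or day, and deviations of same-numbered libraries correlated at 0.04 over genes, so the numbers are not read as pairs. With the replicate number as a block 1274 genes were called, 232 of them lower, and 2239 with the offsets as well, 1041 higher and 1198 lower.

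Of the fixed lists 4 were called in the planned test, against 0 with an estimated correlation, 1 with fry's directional test and 2 to 9 without a library (8 without mutant replicate 1, 9 without control replicate 2). Developmental regulators and fibroblast markers were called in each of the 13 other settings, hair follicle and actin genes in 10. The earlier quasi-likelihood fit does not enter camera, so it gives no list values. Ring1 was called in all 16 alternatives and Rnf2 in none. The odds ratio near the targeted genes was 0.53 and 0.927 within 2 and 20 Mb and 0.867 with DESeq2 calls, none past the threshold. For the 43 other genes that the naming rule picks, 633 of 688 values kept their side of the threshold, 55 no longer passed it and 0 changed direction. Depth limits the genes near the floor of 3 counts.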

Other observations

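The tests of Hox genes, of calcium channel genes and of imprinted genes away from those first noticed, and the choice of symbol families, were made after the main result was seen. The imprinted list was drawn up after 7 of its members had been noticed among the called genes.

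Among 33 families of gene symbols with at least 10 tested members, voltage-gated calcium channel genes had the highest odds ratio, with 9 of 15 tested genes higher and none lower (odds ratio 25.2, 95% interval 7.98 to 86.2, Fisher's exact test, adjusted p = 7.11e-07). Cacna1h rose from 0.582 ± 0.355 to 16.2 ± 0.984 CPM (SD, n = 2 each; log2 fold change 4.74 ± 0.46, adjusted p = 0.00025, edgeR quasi-likelihood test), Cacna1g by 3.47 ± 0.25 and Cacna1c by 2.94 ± 0.32 on the log2 scale. Potassium channel symbols had 10 of 51 higher and 2 lower (adjusted p = 0.00553), while sodium channel symbols (Scn) had 1 of 10 higher (adjusted p = 0.769). Kcna1 (4.94 ± 0.31) was among the potassium channel genes that rose and Kcnj2 (-1.37 ± 0.26) among those that fell. Keratins (8 of 38 higher and 3 lower, adjusted p = 0.00918 for higher) and collagens (7 of 37 higher and 2 lower, adjusted p = 0.0282 for higher) followed, the collagens with the open question of fibroblast RNA in the same libraries. Genes named Cyp were the only family past the threshold for decreases, with 5 of 30 lower and 1 higher (adjusted p = 0.00043). Zinc finger genes named Zfp were called higher less often than others (5 of 353, odds ratio 0.234, adjusted p = 0.00156). Calcium channel genes have long transcripts, which could favour calls. Of 10000 random sets of 15 genes matched on length and level, 0.01% held as many increases, also when matched on the control level, and with the GC content and length offsets 8 were called higher, which argues against length and level as the source.

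Imprinted genes were a hypothesis that came from 7 genes seen among the changes, such as Zdbf2, Sfmbt2 and Meg3 (log2 fold changes 3.38 ± 0.18, 4.55 ± 0.27 and 2.21 ± 0.17). Among the 41 other tested imprinted genes 7 were called, 5 higher and 2 lower, or 17.1% against 6.64% of other genes (odds ratio 2.89, 95% interval 1.08 to 6.66, Fisher's exact test, p = 0.0176). Peg10 (1.84 ± 0.24), Mest (1.33 ± 0.19) and Rian (1.99 ± 0.26) rose, and H19 (-0.74 ± 0.17) fell. Several lie beside genes first noticed, such as Rian and Dlk1 beside Meg3, and Peg10 and Sgce beside Ppp1r9a, so this is not a test on independent genes. Among 29 imprinted genes more than 2 Mb from each gene first noticed 2 were called, or 6.90% against 6.63% of other genes (odds ratio 1.04, interval 0.12 to 4.16, Fisher's exact test, p = 0.719), so the excess was not detectable away from those loci.

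Across the 26 tested Hox genes the log2 fold change rose with the paralog number, which follows the gene's place in its cluster (Spearman's rho = 0.909, permutation p = 1e-05, the smallest that 100000 permutations can give; Pearson's r = 0.761, permutation p = 2e-05). The other 13 Hox genes were not tested, and Hox genes nearly silent in controls pass the low-count filter only with enough reads in the mutant libraries, which favours such a relation. Among those left out, at low counts, Hoxa11 and Hoxd11 had a lower mean in the mutants, and Hoxb1, Hoxd3 and Hoxd4 a higher one. These go against the relation, while Hoxa10, higher in the mutants, goes with it. Across the 22 Hox genes that the control libraries alone would keep, rho was 0.880 (permutation p = 1e-05), and 2 of 6 genes of groups 8 to 13 were called higher. The relation is across genes, which are not independent replicates. A candidate explanation, as a hypothesis, is that PRC1, through its activity or its Ring1 and Rnf2 subunits, lowers some of the posterior Hox genes (rho = 0.880). It would not cover all of them, since Hoxb8 and Hoxb9 (log2 fold change -0.03 and 0.23) were not called, and Hoxc8, which rose, was already at 50.4 CPM in controls. The log2 fold change also followed the control level (rho = -0.73 over the 26 genes and -0.55 over the 22), which itself falls with paralog number (rho = -0.63 and -0.41), so place in the cluster and a low starting level were not separated, and neither was the part of the back from which the skin came.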
